A study of Rattus norvegicus with 36 samples.

How the data were processed

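Granulosa cells, the steroid-producing cells that line the ovarian follicle, were taken by needle puncture from ovaries of immature Sprague Dawley rats aged 21 to 27 days. Per the labels, the cells were plated for 24 h in medium with 5% serum and then moved to serum-free medium with androstenedione, the substrate of aromatase, at 0.1 µM as the series' design text gives it; the sample descriptions give 0.1 M. They were cultured for 48 h with HPTE, the bis-hydroxy metabolite of the pesticide methoxychlor, at 0, 1, 5 or 10 µM. Each dose was given alone (basal), with FSH at 3 ng/ml, or with cAMP at 1 mM, in triplicate. That makes 12 groups of 3 arrays, 36 arrays in all. The form of cAMP added is not given in the sources used here. The labels do not say whether the samples of a group came from separate animals or from separate wells of 1 cell pool, so the p-values measure the spread between samples, part of which may be technical.

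The labels state that 40 ng of total RNA per sample was amplified and biotin labelled with the NuGEN Ovation system before it was put on arrays of 1 type, Affymetrix Rat Genome 230 2.0. The deposited values are intensity values on a linear scale, 1 per probe set and array, which the authors had already background-corrected, normalized and summarised. The processing notes of the labels name RMA, and the series' design text names ArrayAssist. Their versions, and whether all 36 arrays were normalized in 1 run, are not given in the sources used here. The linear scale was read from the values themselves, and the log2 of each intensity was taken before any test. An array has no count depth, so the number of arrays per group limits the precision.

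The table held 31099 probe sets. The 57 control probe sets were set aside, apart from the Gapdh and actin controls used for RNA ratios, which left 31042 tested without a filter on level. Names came from the platform's table and the GRCr8 gene list, which was used for names only. Exactly 1 symbol was given for 20826 probe sets, of which 20758 were brought to the current symbol through the gene identifier. Several symbols were given for 436 probe sets and none for 9780. These stayed in every count but were not named. For each of 14217 genes the probe set with the highest mean over all arrays was used, and 4525 genes had other probe sets as well. Sequences and positions of probes were not analysed here.

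The fit used R 4.3.3 and limma 3.58.1 (lmFit, contrasts.fit, eBayes), with 12 group means, 1 variance per probe set shared over the groups and 24 residual degrees of freedom. Each of 15 comparisons was corrected by Benjamini-Hochberg on its own at an adjusted p under 0.05. They were the response to each stimulus, the difference between both stimuli, each HPTE dose within each stimulus, and 3 interactions at 10 µM. An interaction is the difference between the effects of HPTE in cells of different stimuli. These comparisons, the lists below, the rule for naming genes and most alternatives were chosen before the data were examined. Another 6 comparisons, of stimulated with basal cells at the same HPTE dose, were chosen after seeing the data. Every adjusted p for a gene is limma's, two-sided, and every difference is log2 ± its standard error from the fit with n = 3 arrays against 3.

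The 21 gene lists held 389 written members, of which 342 were measured. The other members were not analysed here. The lists were steroidogenesis, granulosa differentiation, ovulatory response, cAMP-PKA response, cholesterol biosynthesis, AhR and xenobiotic response, Nrf2 oxidative stress, estrogen-responsive genes, androgen-responsive genes, ER stress and amino acid response, p53 and apoptosis, proliferation, extracellular matrix, actin cytoskeleton and smooth muscle, hypoxia and glycolysis, and interferon response. Markers of theca and stroma, macrophages and leukocytes, endothelium, oocytes and surface epithelium completed them. Each list was tested with camera from limma at a preset correlation of 0.01, with Benjamini-Hochberg over the 21 lists in 5 main comparisons. The same test was run with an estimated correlation. Members were also counted by the test over all probe sets and "adjusted over the list alone". A further pair of tests followed genes that responded to 1 stimulus by at least 2-fold, chosen on these arrays, under HPTE in cells given the other stimulus.

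Genes named in the text followed a written rule. In each main comparison these were the 8 with the largest rise and the 8 with the largest fall among genes that passed and whose treated and control arrays did not overlap. At 1 and 5 µM they were the same genes and the 5 largest in each direction, and in interactions the 5 largest in each direction. Members of the lists could be named whether they passed or not. Of the 2624 probe sets called for 10 µM HPTE with FSH, 2601 differed in the called direction in all 3 pairs of arrays with the same number. The matching counts were 2490 of 2502 for FSH, 2219 of 2228 for cAMP, 316 of 316 for 10 µM HPTE alone and 520 of 525 with cAMP. Among the named genes that passed in these comparisons, the exceptions were Kitlg under 10 µM HPTE with FSH and Xbp1 under 10 µM HPTE with cAMP.

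The titles number the arrays of a group 1 to 3, and no label says that equal numbers share a cell preparation. Pairing was therefore checked in the values. After removal of group means, arrays of different groups with the same number correlated above 0.1 in 189 of 198 cases, and for all 36 arrays the closest array of another group had the same number. The mean correlation was 0.736 among arrays numbered 3 and -0.509 between numbers 1 and 3. It was 0.393 among arrays numbered 1, 0.368 among those numbered 2 and 0.296 between numbers 1 and 2. Most of the pairing thus set number 3 against the rest. Removing the mean of 3 arrays by itself pushes correlations between numbers downward. The planned fit had no block, so the fit with the number as a block (22 residual degrees of freedom) is given beside it, as are numbers 1 and 2 alone.

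Alternatives were the block, a filter on dim probe sets, the arrays of the compared groups only, quantile normalization, eBayes with trend and robust options, the mean of all probe sets of a gene, sets without a fold limit, and leaving out each number and each array. Chosen after seeing the data were leaving out a pair of doubted arrays (number 2 of the unexposed FSH group and of the unexposed cAMP group), that setting with the block, and a 2-level batch of number 3 against the others. Correlations and covariances expected for comparisons that share a control group were taken from 20 simulations without any effect. Figures were drawn with Python 3.11.15.

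The fit was tested on simulated data with the same groups and spread, 5 times with 31042 probe sets. Without a block it found 10.1% of changes of 1.41-fold, 62.7% of 2-fold and 94.8% of 4-fold, and 0.89% of its calls were false. With the block the shares were 29%, 88.1% and 99.7%, with 4.63% of calls false. The list test found 10 of 10 planted lists and called 1 of 200 lists without a change. Genes were simulated there as independent and without differences between array numbers. In the data the cholesterol biosynthesis list had an estimated correlation of 0.456, so this share of false lists does not carry over to the real lists. No array was left out of the results unless stated. The scanner files were not used here.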

Results

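Transcript levels were measured in cultured rat ovarian granulosa cells on 36 arrays. The cells had received no stimulus, follicle-stimulating hormone (FSH) or cAMP, each with 0, 1, 5 or 10 µM of the methoxychlor metabolite HPTE, and each of the 12 groups held 3 arrays numbered 1 to 3. Methoxychlor is an organochlorine pesticide, and HPTE is known to bind estrogen receptors. FSH acts through a membrane receptor that raises cAMP inside the cell, so cAMP given directly is a stimulus that does not need the receptor. The series asks how HPTE changes the transcripts of these cells at rest and under each stimulus. Arrays give no count depth; the median intensity per array lay between 65.8 and 73.7, and arrays of 1 group correlated at 0.95 to 0.994 over all probe sets.

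The arrays numbered 3 stood apart from the others on the second principal component and in RNA ratios. The first principal component of the 36 arrays held 34% of the variance. The cAMP arrays and the unexposed FSH arrays lay at one end of it and the basal arrays and the FSH arrays at 5 and 10 µM HPTE at the other. The FSH arrays at 1 µM were spread between. The second held 27.2% and separated number 3 from numbers 1 and 2. By the median absolute log2 difference, number 1 was nearer to number 3 than to number 2 at 1 µM HPTE in basal cells (0.207 against 0.235) and with FSH (0.212 against 0.251). The log2 ratio of the 3' to the 5' control probe set of Gapdh, a sign of RNA integrity and amplification, was 0.767 to 1.07 in number 3 and 1.61 to 2.4 in numbers 1 and 2. Group means lay between 1.49 and 1.86 (n = 3 each). Compared between arrays of equal number, a test chosen after seeing the data, the ratio was lower in 3 of 3 pairs at 10 µM HPTE than at 0 µM in basal cells (mean -0.16) and at 1, 5 and 10 µM than at 0 µM with FSH (-0.119, -0.054 and -0.168). It was also lower in 3 of 3 pairs at 1 µM with FSH (-0.316) and with cAMP (-0.343) than in basal cells. The actin ratio was lower in 3 of 3 pairs at 10 µM than at 0 µM in basal cells (mean -0.168). The same held at 1 µM against 0 µM with cAMP (-0.318). It also held for FSH against basal cells at 1 and 10 µM (-0.126 and -0.215) and against cAMP at 0 µM (-0.208). At 1 and 5 µM with FSH it was higher than at 0 µM in 2 of 3 pairs. A permutation test of the groups within numbers (10000 permutations of 36 arrays) gave p = 0.069 for Gapdh and 0.532 for actin, so a smaller difference in RNA quality between groups is not excluded. Every group held 1 array of each number, so the numbers were balanced over the groups. Counts over all probe sets from the fit with the number as a block and from numbers 1 and 2 alone are therefore given beside the main counts.

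**Figure D1:**
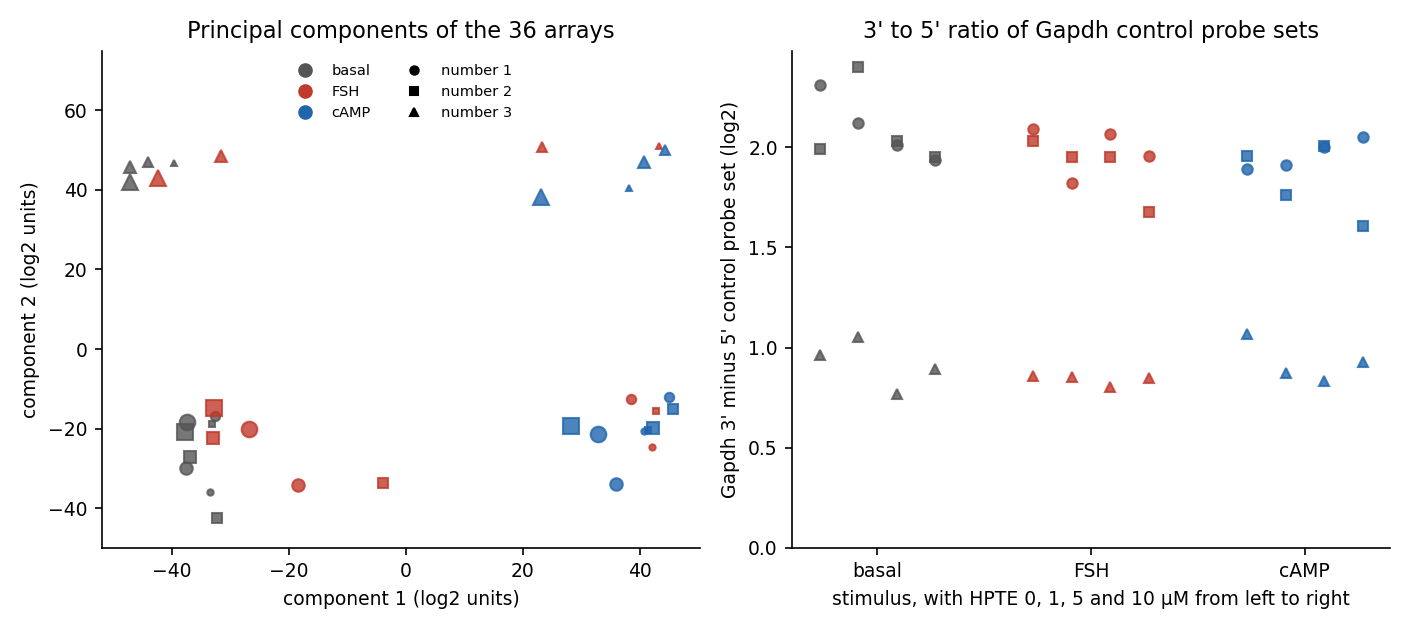
Left, the first and second principal components of the log2 values (log2 units), with 1 point per array, color for the stimulus, shape for the array number and larger points for higher HPTE doses; number 3 lies above numbers 1 and 2. Right, the log2 ratio of 3' to 5' Gapdh control probe sets per array, below 1.1 in every array numbered 3 and above 1.6 in all others.

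FSH raised genes of steroid synthesis and of the mature granulosa cell. Cyp19a1, the aromatase that turns androgens into estrogens, was 43.3-fold higher with FSH than in basal cells (log2 5.44 ± 0.95, adjusted p = 0.000229, n = 3 arrays each). Cyp11a1, which cleaves the cholesterol side chain at the start of steroid synthesis, was 31.2-fold higher (4.97 ± 0.79). Crabp2, a retinoic acid binding protein, was 36.6-fold higher (5.19 ± 0.53), and the prolactin receptor Prlr was 24.4-fold higher (4.61 ± 0.75). Hao2, a peroxisomal hydroxy acid oxidase, rose by 4.43 ± 0.4. Smooth muscle actin Acta2 was 23.6-fold lower (-4.56 ± 0.55), the decoy receptor Tnfrsf11b (osteoprotegerin) 18.1-fold lower (-4.17 ± 0.42), and the opioid precursor Penk 17.7-fold lower (-4.15 ± 0.45). The luteinizing hormone receptor Lhcgr was 20.3-fold higher (4.34 ± 1, adjusted p = 0.00416), a call lost without number 3 of the FSH arrays (adjusted p = 0.066). Single arrays moved some of these values by more than 1.5-fold. Cyp19a1 was at 4.76, 6.77 and 4.78 without numbers 1, 2 and 3 of the FSH arrays. Lhcgr was at 5.99 and 3.21 and Prlr at 5.44 and 3.9 without numbers 2 and 3, and Acta2 at -5.2 without number 3. Cyp11a1 was at 5.56 and 4.26 without numbers 1 and 3 of the basal arrays.

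Of 17 measured genes of the steroidogenesis list, 12 rose with FSH, none fell and 5 did not pass; adjusted over the list alone, 12 rose (median log2 2.41, camera adjusted p = 4.6e-14, 0.00591 with an estimated correlation). Star, which brings cholesterol into mitochondria, rose by 2.92 ± 0.54, the steroid dehydrogenase Hsd3b1 by 3.43 ± 0.42, Hsd17b1 by 4.14 ± 0.63, and the transcription factor Nr5a1 (SF-1) by 2.54 ± 0.23. In the granulosa differentiation list 10 of 22 genes rose and 1 fell (13 and 3 adjusted over the list alone; median 0.868, adjusted p = 3.04e-06, 0.0314 with an estimated correlation). The inhibin subunits Inha and Inhbb rose by 2.68 ± 0.35 and 2.52 ± 0.36, while Igf1 fell by 1.53 (SE 0.25). All but 2 of the 16 genes of the actin and smooth muscle list fell, 14 also when adjusted over the list alone (median -1.56, adjusted p = 2.23e-19, 0.0065 with an estimated correlation), among them Tagln (-3.46 ± 0.74, -4.28 without number 3 of the FSH arrays) and Myl9 (-2.68 ± 0.41). In the extracellular matrix list 9 of 22 fell and 2 rose, the same counts as adjusted over the list alone (median -0.62, adjusted p = 3.35e-05, 0.0065 with an estimated correlation). Fibronectin (Fn1) changed by -3.11 ± 0.46 and osteopontin (Spp1) by -3.36 ± 0.54, while the protease inhibitor Timp3 rose by 0.99 ± 0.19.

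Another 5 lists passed with FSH at the preset correlation but not with an estimated one. In the cAMP-PKA response list 7 of 23 genes rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.00243, but adjusted p = 0.26 with an estimated correlation); the kinase Sik1 rose by 2.35 ± 0.29 and the phosphodiesterase Pde4b by 1.74 ± 0.28. In the ovulatory response list 4 of 19 rose and none fell (6 adjusted over the list alone; adjusted p = 0.00916, but adjusted p = 0.39 with an estimated correlation), including the vesicle protein Snap25 (2.44 ± 0.42). In the cholesterol biosynthesis list 3 of 20 rose and none fell, 3 also adjusted over the list alone, with Dhcr7 at 1.06 ± 0.23 (adjusted p = 0.0351, but adjusted p = 0.689 with an estimated correlation and 0.065 with the block). In the ER stress and amino acid list 4 of 20 fell and 1 rose, the same counts as adjusted over the list alone (adjusted p = 0.00291, but adjusted p = 0.504 with an estimated correlation); the lipoprotein receptor Vldlr fell by 2.08 (SE 0.18) and asparagine synthetase Asns by 1.26 (SE 0.3). In the proliferation list 1 of 30 fell and none rose, by either count (median -0.21, adjusted p = 0.0375, but adjusted p = 0.689 with an estimated correlation). The AhR and xenobiotic list did not pass (adjusted p = 0.0964, 0.0422 with the block).

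Over all probe sets limma called 2502 for FSH, 1204 higher and 1298 lower, of which 531 and 746 differed at least 2-fold. The fit with the block called 4984, 2656 higher and 2328 lower. Numbers 1 and 2 alone gave 2013, 823 higher and 1190 lower. Which direction held more calls thus depended on the fit.

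cAMP lowered contractile genes and raised genes of steroid synthesis. Acta2 was 27.1-fold lower with cAMP than in basal cells (-4.76 ± 0.55, adjusted p = 7.59e-07, n = 3 arrays each), and the actin-binding protein Tagln was 19.5-fold lower (-4.29 ± 0.74). Carboxypeptidase E (Cpe), which processes peptide hormones, was 17.6-fold lower (-4.14 ± 0.46). Crabp2 was 23.3-fold higher (4.54 ± 0.53), Cyp11a1 17.8-fold higher (4.15 ± 0.79), and the methyltransferase Inmt 20.8-fold higher (4.38 ± 0.57). The glutathione transferase Gstm7 rose by 3.67 ± 0.39. Cyp19a1 was 12.6-fold higher (3.66 ± 0.95, adjusted p = 0.0135), a call lost without number 2 of the basal arrays (adjusted p = 0.0522) or number 2 of the cAMP arrays (adjusted p = 0.144). Cyp19a1 was at 2.34 and 4.61 without numbers 2 and 3 of the cAMP arrays. Tagln was at -3.6 and -4.98 without numbers 1 and 2, and Cyp11a1 at 4.88 without number 3. Without numbers 1 and 3 of the basal arrays Cyp11a1 was at 4.75 and 3.45.

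In the steroidogenesis list 10 of 17 genes rose with cAMP and none fell (11 adjusted over the list alone; median 2.24, adjusted p = 1.51e-09, 0.0121 with an estimated correlation), among them Hsd3b1 (3.34 ± 0.42) and Nr5a1 (2.28 ± 0.23). In the granulosa differentiation list 8 of 22 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 1.61e-05, 0.0496 with an estimated correlation), with Inha at 2.42 ± 0.35 and Igf1 at -2.07 ± 0.25. In the actin list 14 of 16 fell (15 adjusted over the list alone; median -1.46, adjusted p = 1.98e-18, 0.0065 with an estimated correlation). In the extracellular matrix list 8 of 22 fell and 1 rose (12 and 2 adjusted over the list alone; median -0.87, adjusted p = 0.000101, 0.00859 with an estimated correlation), with Fn1 at -3.31 ± 0.46 and Spp1 at -3.57 ± 0.54. In the ER stress and amino acid list 6 of 20 fell (9 fell and 1 rose adjusted over the list alone; adjusted p = 2.58e-05, but adjusted p = 0.26 with an estimated correlation), with Asns at -1.81 ± 0.3 and Vldlr at -2.21 ± 0.18. In the proliferation list 2 of 30 fell, by either count (median -0.41, adjusted p = 7e-04, but adjusted p = 0.465 with an estimated correlation). In the AhR and xenobiotic list 1 of 14 rose, the transporter Abcc3 (0.7 ± 0.16), and 3 adjusted over the list alone (adjusted p = 0.0264, but adjusted p = 0.137 with an estimated correlation). The cAMP-PKA list did not pass (5 of 23 rose and 3 fell, by either count; adjusted p = 0.221). Nor did the ovulatory list (2 of 19 rose and 2 fell, by either count; 0.73) or the cholesterol biosynthesis list (1 of 20 rose, by either count; median -0.24, 0.574).

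Over all probe sets limma called 2228 for cAMP, 835 higher and 1393 lower, of which 359 and 766 differed at least 2-fold. The block gave 4709, 1998 of them higher, and numbers 1 and 2 alone 2032, 914 of them higher. Of the probe sets called for FSH and for cAMP, 703 were higher and 1086 lower under both, where independent calls would give 32.4 and 58.2, and none moved in opposite directions. The effects of FSH and cAMP correlated at 0.906 across all probe sets, which are not independent replicates. Both effects use the same 3 basal arrays. They also include number 2 of the unexposed FSH and cAMP arrays, which looked exchanged, as described below. If they were exchanged, the likeness of both effects would be overstated. Without this pair 680 probe sets differed between FSH and cAMP, and the correlation without it was not analysed here. Simulations without any effect gave a correlation of 0.5, a covariance of 0.0306 against 0.2 in the data, and 0 shared calls. Without an effect hardly any probe set is called, so this 0 cannot show how many real shared calls come from the common arrays. Part of the excess of shared calls may come from the shared arrays. In a comparison chosen after seeing the data, which shares no arrays with the effect of FSH, the 315 genes raised at least 2-fold by FSH had a median of 1.22 for cAMP against basal cells at 1 µM HPTE, and 207 were called higher.

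Compared directly, FSH and cAMP gave no probe set past limma's threshold at 0 µM HPTE, while 1002 had an unadjusted p under 0.05, fewer than expected without any effect. The count was 0 with the block, with quantile normalization and in numbers 1 and 2 alone as well, but not without the arrays named below. Cyp19a1 was 3.43-fold higher with FSH (1.78 ± 0.95, adjusted p = 1), and its level differed among arrays of 1 group. It was 11.5 in numbers 1 and 3 of the FSH group and 7.48 in number 2, against 7.62 and 6.46 in numbers 1 and 3 of the cAMP group and 11 in number 2 (log2 intensity). Lhcgr showed the same arrangement, at 10.3, 5.94 and 11.5 with FSH and 5.66, 10 and 5.8 with cAMP. Without number 2 of the FSH group 59 probe sets passed. Without number 2 of both groups, a setting chosen after seeing the data, 680 passed, 447 higher with FSH and 233 lower, and 2454 with the block, 1659 higher and 795 lower.

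With HPTE alone few probe sets passed below 10 µM. At 1 µM in basal cells no probe set passed limma's test, 159 had an unadjusted p under 0.05, and the block and numbers 1 and 2 alone also gave 0. At 5 µM 4 passed, 2 in each direction, with 527 at an unadjusted p under 0.05. The block gave 36, 9 higher and 27 lower, and numbers 1 and 2 alone gave 0. At both doses the unadjusted count lay under the share of 0.05 expected without any effect, so few calls do not show that HPTE had no effect. The 4 were Esm1, an endothelial proteoglycan (1.37 ± 0.23, adjusted p = 0.0232), the urea transporter Slc14a1 (1.03 ± 0.19), the sulfotransferase Sult1a1 (-1.27 ± 0.22), and Cdc42ep2, an effector of a small GTPase (-1.09 ± 0.17). Leaving out any single array of the compared groups left 0 or 1 of them past the threshold.

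At 10 µM in basal cells, genes of mitosis fell. Kif11, a motor of the mitotic spindle, was 2.77-fold lower than without HPTE (-1.47 ± 0.19, adjusted p = 4.15e-05, n = 3 arrays each), and the kinetochore protein Cenpf was 2.26-fold lower (-1.17 ± 0.17). Trib3, a pseudokinase induced in amino acid and ER stress, was 5.07-fold higher (2.34 ± 0.36, adjusted p = 0.000441), and the cationic amino acid transporter Slc7a3 5.64-fold higher (2.5 ± 0.36). The aldo-keto reductase Akr1b8 was 5.78-fold higher (2.53 ± 0.38) and the inflammatory caspase Casp4 4-fold higher (2 ± 0.26). Cyp26b1, which degrades retinoic acid, was 5.83-fold lower (-2.54 ± 0.42) and lipoprotein lipase (Lpl) 3.81-fold lower (-1.93 ± 0.27). Star was 5.6-fold higher (2.49 ± 0.54, adjusted p = 0.0159), but the call was lost without number 1 of the exposed arrays (adjusted p = 0.104), number 2 of the unexposed (0.0664) or number 3 of the unexposed (0.108).

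In the proliferation list 14 of 30 genes fell at 10 µM and none rose (26 fell adjusted over the list alone; median -1.07, camera adjusted p = 3.01e-47, 0.000485 with an estimated correlation), including Top2a (-1.33 ± 0.24) and Bub1 (-1.36 ± 0.23). In the ER stress and amino acid list 3 of 20 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.362, adjusted p = 6.32e-06, but adjusted p = 0.221 with an estimated correlation); the stress-induced Sesn2 rose by 0.64 ± 0.11. In the Nrf2 list, of genes induced by oxidative stress, none of 18 passed over all probe sets and 5 rose adjusted over the list alone (median 0.307, adjusted p = 0.00708, but adjusted p = 0.356 with an estimated correlation). Another 3 lists passed downward at the preset correlation only. None of 22 granulosa differentiation genes passed (1 rose and 1 fell adjusted over the list alone; adjusted p = 0.0319, but adjusted p = 0.433 with an estimated correlation). None of 20 cholesterol biosynthesis genes passed by either count (adjusted p = 0.0408, but adjusted p = 0.689 with an estimated correlation). None of 16 actin genes passed (1 fell adjusted over the list alone; adjusted p = 0.00189, but adjusted p = 0.433 with an estimated correlation). In the AhR and xenobiotic list 1 of 14 rose, Cyp1b1 (1.25 ± 0.27, adjusted p = 0.0149), which the AhR and estrogens are known to regulate; the list did not pass (adjusted p = 0.179), and the call of Cyp1b1 was lost without number 2 of the unexposed (adjusted p = 0.124) or number 3 of the exposed arrays (0.153).

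Over all probe sets limma called 316 at 10 µM in basal cells, 129 higher and 187 lower, with 1999 at an unadjusted p under 0.05. The block gave 1059, 499 of them higher, and numbers 1 and 2 alone 151, 67 of them higher. The count was 196, 162 and 176 without numbers 1, 2 and 3 of the unexposed arrays and 194 without number 3 of the exposed arrays.

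In FSH-stimulated cells HPTE moved a large part of the genes that FSH had moved back toward their basal level. At 10 µM Cyp19a1 was 27.2-fold lower than with FSH alone (-4.77 ± 0.95, adjusted p = 0.00103, n = 3 arrays each), Cyp11a1 20.7-fold lower (-4.37 ± 0.79) and Prlr 19.1-fold lower (-4.26 ± 0.75). The matrix-associated protein Smoc2 was 31.4-fold lower (-4.98 ± 0.39) and Hao2 17.7-fold lower (-4.15 ± 0.4). Pamr1, a secreted protein of muscle, was 32-fold higher (5 ± 0.39), Tnfrsf11b 19.4-fold higher (4.28 ± 0.42), Fn1 13.4-fold higher (3.74 ± 0.46) and Slc7a3 14.6-fold higher (3.86 ± 0.36). Of these, Smoc2 also fell and Slc7a3 also rose at this dose in basal cells and with cAMP. Their changes can therefore not be read as a return toward the basal level alone. Star did not follow Cyp11a1: it differed by -0.27 ± 0.54 (adjusted p = 0.948), and 1 other probe set of Star had the opposite sign. HPTE alone had raised Star in basal cells at this dose, as given above. The small difference of Star therefore does not show that its response to FSH was kept. Lhcgr was 17.6-fold lower (-4.14 ± 1, adjusted p = 0.00633), a call lost without number 3 of the unexposed FSH arrays (adjusted p = 0.0878). Without numbers 1, 2 and 3 of the unexposed arrays Cyp19a1 was at -4.1, -6.1 and -4.11. Without numbers 2 and 3 Lhcgr was at -5.78 and -3.01 and Prlr at -5.08 and -3.55. Cyp11a1 was at -3.76 without number 3 of the exposed arrays.

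**Figure D2:**
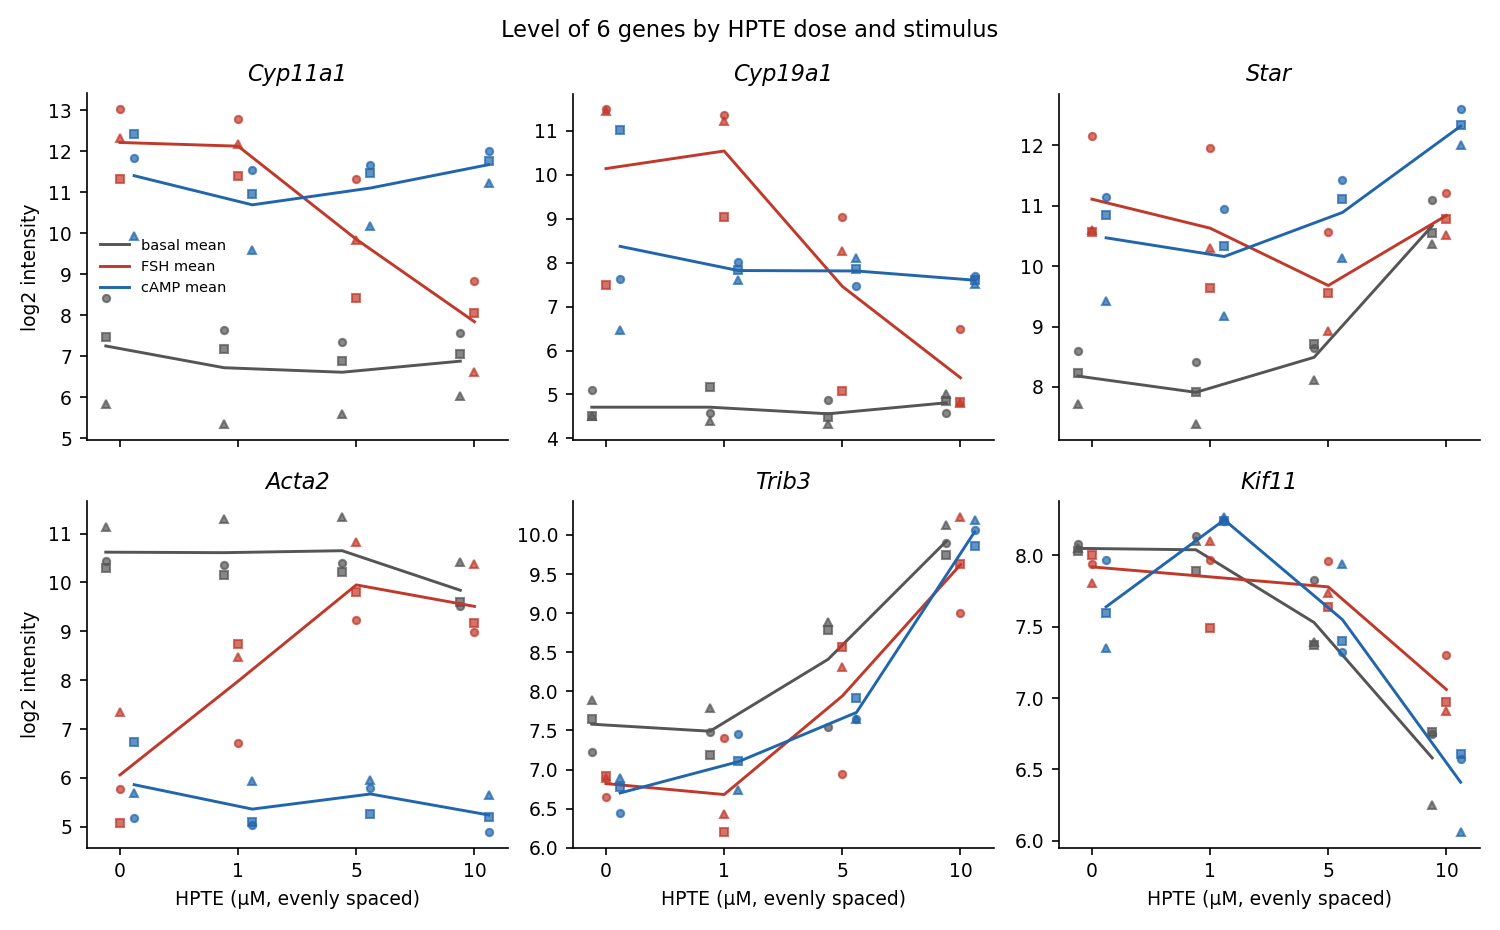
Log2 intensity of 6 genes (vertical axes) at each HPTE dose (horizontal axes, µM), with 1 point per array shaped by number (circle 1, square 2, triangle 3) and lines through the mean of 3 arrays in basal, FSH and cAMP cells. With FSH the mean of Cyp11a1 went from 12.2 at 0 µM to 7.84 at 10 µM, while with cAMP it was 11.4 and 11.7.

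The lower dose gave a similar picture. At 5 µM with FSH, Nr5a1 was 4.73-fold lower (-2.24 ± 0.23, adjusted p = 2.93e-07) and the renal injury molecule Havcr1 11.9-fold lower (-3.58 ± 0.55, -4.47 without number 2 of the unexposed arrays), while Acta2 was 14.8-fold higher (3.89 ± 0.55, 4.53 without number 3) and Penk 13.8-fold higher (3.79 ± 0.45). Cyp19a1 differed by -2.68 ± 0.95 (adjusted p = 0.102) and Cyp11a1 by -2.36 ± 0.79 (adjusted p = 0.0757), and neither passed. With the block both did (0.0451 and 0.001). The unexposed FSH mean of Cyp19a1 includes the doubted array numbered 2, which stood far below numbers 1 and 3. At 1 µM with FSH 2 probe sets passed, both higher, with 896 at an unadjusted p under 0.05, fewer than expected without any effect. They belonged to Tnfrsf11b (2.62 ± 0.42, adjusted p = 0.0254) and Pamr1 (2.37 ± 0.39, adjusted p = 0.0254). Without numbers 1 and 2 of the exposed arrays Tnfrsf11b was at 3.48 and 1.98, and Pamr1 at 3.14 and 1.76. At 1 µM the count was 30 with the block, 0 in numbers 1 and 2 alone, and without the pair of doubted arrays 23, or 254 with the block. It was 74 without number 1 of the exposed arrays, 5 without number 2 of the unexposed, and 0 without any other single array.

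In the steroidogenesis list 9 of 17 genes fell at 10 µM with FSH and none rose (12 fell adjusted over the list alone; median -1.42, adjusted p = 4.5e-08, 0.0252 with an estimated correlation), among them Nr5a1 (-2.71 ± 0.23) and the lipoprotein receptor Scarb1 (-3.03 ± 0.51, -3.74 without number 2 of the unexposed arrays). In the granulosa differentiation list 11 of 22 fell and 3 rose (12 and 3 adjusted over the list alone; median -0.66, adjusted p = 4.78e-05, but adjusted p = 0.069 with an estimated correlation); Inha changed by -2.32 ± 0.35 and the granulosa transcription factor Foxl2 by -0.75 ± 0.12, while Igf1 rose by 1.36 ± 0.25. In the actin list 11 of 16 rose and none fell (13 rose adjusted over the list alone; median 1.06, adjusted p = 7.51e-12, 0.0286 with an estimated correlation), with Acta2 at 3.45 ± 0.55 (4.08 without number 3 of the unexposed arrays) and Myl9 at 1.85 ± 0.41. In the extracellular matrix list 8 of 22 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.297, adjusted p = 4.78e-05, 0.0065 with an estimated correlation); Spp1 rose by 2.93 ± 0.54 and Timp3 fell by 1.14 (SE 0.19).

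In the ER stress and amino acid list 9 of 20 genes rose at 10 µM with FSH and 1 fell (11 and 2 adjusted over the list alone; median 0.625, adjusted p = 2.16e-08, but adjusted p = 0.0972 with an estimated correlation), with Trib3 at 2.8 ± 0.36, Asns at 1.88 ± 0.3, the glutathione-degrading Chac1 at 1.62 ± 0.29 and Vldlr at 1.78 ± 0.18. In the proliferation list 8 of 30 fell and none rose (12 fell adjusted over the list alone; median -0.67, adjusted p = 1.22e-08, but adjusted p = 0.124 with an estimated correlation), with Top2a at -1.28 ± 0.24 and Kif11 at -0.86 ± 0.19. In the cholesterol biosynthesis list 3 of 20 fell and none rose (5 fell adjusted over the list alone; adjusted p = 0.00291, but adjusted p = 0.578 with an estimated correlation), with Hsd17b7, which also belongs to the steroidogenesis list, at -2 ± 0.44 and Dhcr7 at -1.02 ± 0.23. The cAMP-PKA list did not pass (5 of 23 fell and 2 rose, 8 and 2 adjusted over the list alone; adjusted p = 0.102), nor did the ovulatory list (4 of 19 fell, 6 fell and 1 rose adjusted over the list alone; adjusted p = 0.0743).

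Over all probe sets limma called 2624 at 10 µM with FSH, 1399 higher and 1225 lower, and 2029 at 5 µM, 1072 higher and 957 lower. The block gave 5333 and 4426, of which 2629 and 1987 were higher. Numbers 1 and 2 alone gave 1972 and 1414, of which 1213 and 873 were higher. The larger direction thus depended on the fit. Of the calls at 5 µM, 939 higher and 773 lower were called the same way at 10 µM, where independent calls would give 48.3 and 37.8. Both doses share the unexposed FSH arrays. Simulations without effects gave a covariance of 0.0305 against 0.193 in the data. The simulated value is what shared arrays give at the measured spread. Part of the excess of shared calls may still come from these arrays. The 0 shared calls of the simulations are no measure here, since hardly any probe set is called without an effect. The effects of FSH and of 10 µM HPTE with FSH also share these arrays: 802 probe sets raised by FSH fell with HPTE and 930 lowered by FSH rose, against 47.5 and 58.5 for independent calls, and 2 and 2 moved the same way. Their covariance was -0.199 against -0.0305 in the simulations, where only the shared arrays give a covariance. Part of the excess of opposite calls may still come from these arrays. The effects of cAMP and of 10 µM HPTE with FSH share no arrays: 537 probe sets raised by cAMP fell with HPTE and 890 lowered by cAMP rose, against 33 and 62.8 for independent calls. The covariance of these effects was -0.174 against 0.000172 in the simulations.

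**Figure D3:**
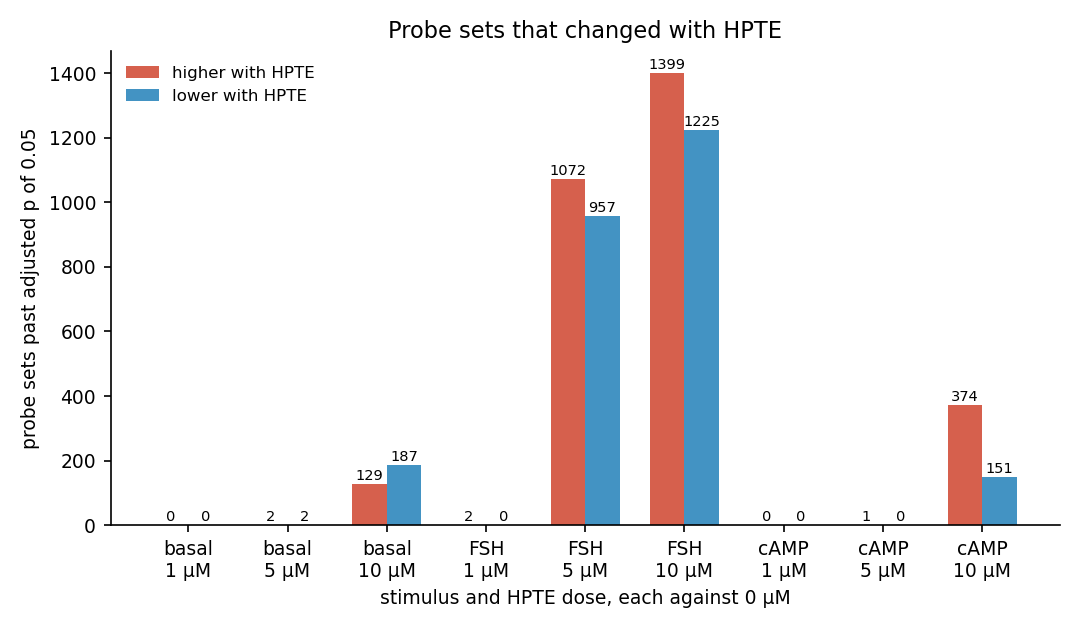
Number of probe sets past an adjusted p of 0.05 in limma for each HPTE dose against 0 µM within each stimulus (bars from 0, higher and lower apart). At 10 µM the totals were 316 in basal cells, 2624 with FSH and 525 with cAMP.

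In cAMP-stimulated cells HPTE raised stress genes. At 10 µM the reductase Akr1c15 was 11.3-fold higher than with cAMP alone (3.49 ± 0.19, adjusted p = 9.43e-13, n = 3 arrays each), Trib3 10.1-fold higher (3.34 ± 0.36), Slc7a3 10.1-fold higher (3.34 ± 0.36) and the transcription factor Atf5 7.43-fold higher (2.89 ± 0.33). AMP deaminase Ampd3 was 8.1-fold higher (3.02 ± 0.45) and the adhesion molecule Vcam1 7.31-fold higher (2.87 ± 0.36). The secretory granule protein Scg2 was 7.77-fold lower (-2.96 ± 0.49) and the potassium channel Kcnd2 7.25-fold lower (-2.86 ± 0.37). Cyp11a1 differed by 0.27 ± 0.79 (adjusted p = 0.999), Cyp19a1 by -0.77 ± 0.95 (adjusted p = 0.969) and Star by 1.85 ± 0.54 (adjusted p = 0.0929, 0.000143 with the block). The unexposed cAMP mean of Cyp19a1 includes the doubted array numbered 2, which stood far above numbers 1 and 3, so its difference depends on that array.

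In the ER stress and amino acid list 11 of 20 genes rose at 10 µM with cAMP and none fell (14 rose adjusted over the list alone; median 0.907, adjusted p = 8.06e-21, 0.0065 with an estimated correlation), with Asns at 2.47 ± 0.3, Chac1 at 2.31 ± 0.29 and the serine synthesis enzyme Psat1 at 1.23 ± 0.24. In the proliferation list 12 of 30 fell and none rose (27 fell adjusted over the list alone; median -0.99, adjusted p = 3.68e-32, 0.00339 with an estimated correlation), with Top2a at -1.65 ± 0.24 and Bub1 at -1.44 ± 0.23. In the Nrf2 list 4 of 18 rose and none fell (8 rose adjusted over the list alone; median 0.602, adjusted p = 2.86e-10, 0.00939 with an estimated correlation), with the quinone reductase Nqo1 at 2.3 ± 0.37 and the cystine transporter Slc7a11, also in the ER stress list, at 2.17 ± 0.43. In the hypoxia and glycolysis list 1 of 16 rose, Vegfa (0.85 ± 0.13), and 4 rose adjusted over the list alone (median 0.318, adjusted p = 7e-04, 0.0314 with an estimated correlation). In the interferon list 3 of 13 rose and none fell (5 rose adjusted over the list alone; median 0.385, adjusted p = 7e-04, 0.0105 with an estimated correlation); the proteasome subunit Psmb8 rose by 1.03 ± 0.24, a call lost without number 1 of the unexposed (adjusted p = 0.133), number 1 of the exposed (0.0708) or number 3 of the exposed arrays (0.109). In the actin list none of 16 passed (2 fell adjusted over the list alone; adjusted p = 0.0264, but adjusted p = 0.578 with an estimated correlation). The steroidogenesis list did not pass (0 of 17 over all probe sets, 1 rose adjusted over the list alone, 2 rose and 1 fell with the block; adjusted p = 0.73); its median was 0.07 and its mean 0.009, while camera's direction was downward.

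Over all probe sets limma called 525 at 10 µM with cAMP, 374 higher and 151 lower, with 2907 at an unadjusted p under 0.05. The block gave 1810, 1206 of them higher, numbers 1 and 2 alone 330, 184 of them higher, and leaving out the pair of doubted arrays 792, 551 of them higher. The excess of higher calls was thus smaller in numbers 1 and 2. The count was 347 without number 1 of the unexposed arrays and 278 without number 3 of the exposed. At 5 µM with cAMP 1 probe set passed, for Ampd3 (3.07 ± 0.45, adjusted p = 0.00808), with 2624 at an unadjusted p under 0.05; the block gave 23, numbers 1 and 2 alone 1, and leaving out the pair of doubted arrays 0, but 627 with the block, 290 higher and 337 lower. The call of Ampd3 was lost without numbers 2 (adjusted p = 0.0954) or 3 (0.103) of the unexposed arrays or numbers 1 (0.0734) or 2 (0.101) of the exposed, and without number 1 of the unexposed arrays 6 probe sets passed. At 1 µM with cAMP none passed in limma, 743 had an unadjusted p under 0.05 (fewer than expected without any effect), the block gave 7 and numbers 1 and 2 alone 1. There 9 passed without number 1 of the unexposed arrays and 2 without number 3 of the exposed.

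Calls at 10 µM overlapped between the stimuli. Of the probe sets called in basal cells, 56 higher and 72 lower were called the same way with cAMP, where independent calls would give 1.55 and 0.91. With FSH, 72 of the probe sets lower in basal cells were lower too, against 7.38, and across all probe sets the effects in basal and FSH cells correlated at 0.323. With FSH and with cAMP 180 were higher and 88 lower under both, against 16.9 and 5.96. These comparisons share no arrays. Trib3 and Slc7a3 rose and Kif11 and Top2a fell at 10 µM under each of the 3 conditions.

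The effect of 10 µM HPTE differed between stimuli for many genes when the difference itself was tested. With FSH the effect lay above that in basal cells for Acta2 (by 4.23 ± 0.77, adjusted p = 0.0022, 4.86 without number 3 of the unexposed FSH arrays) and Tnfrsf11b (4.14 ± 0.6), and below it for Hao2 (-4.15 ± 0.57) and Crabp2 (-4.04 ± 0.75); limma called 674, 427 higher and 247 lower. The block gave 2102, 1193 of them higher. Numbers 1 and 2 alone gave 154, 122 of them higher, and leaving out the pair of doubted arrays 1059, 565 of them higher. The count was 437 without number 1 and 428 without number 2 of the basal arrays at 10 µM, and 398 without number 3 of the FSH arrays at 10 µM. With cAMP the effect lay above that in basal cells for Reg3g, an antibacterial lectin (2.54 ± 0.29, adjusted p = 4.85e-05), and Akr1c15 (1.98 ± 0.26), and below it for the protease inhibitor Serpinb1a (-1.79 ± 0.29). Here limma called 40, 34 higher and 6 lower; the block gave 177, 148 of them higher, numbers 1 and 2 alone 17, 14 of them higher, and leaving out the pair of doubted arrays 70, or 527 with the block. The count was 26 without number 1 of the unexposed basal arrays and 24 without number 3 of the cAMP arrays at 10 µM.

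HPTE also acted differently on FSH and cAMP cells. At 10 µM its effect was more negative with FSH than with cAMP for Scarb1 (-4.07 ± 0.73, adjusted p = 0.0015, -4.79 without number 2 of the FSH arrays at 0 µM) and Nr5a1 (-2.09 ± 0.32, adjusted p = 0.000451), and more positive for Acta2 (4.07 ± 0.77, 4.71 without number 3 of the same group) and the angiotensin receptor Agtr2 (5.05 ± 1.02). Agtr2 was at 4.44 and 6.01 without numbers 1 and 2 of the FSH arrays at 0 µM and 5.67 without number 2 of the cAMP arrays at 0 µM. For Cyp11a1 the difference was -4.64 ± 1.11 (adjusted p = 0.0225), a call lost without number 1 (adjusted p = 0.0739) or number 3 (0.0533) of the FSH arrays at 0 µM, number 3 of the FSH arrays at 10 µM (0.0931), number 3 of the cAMP arrays at 0 µM (0.0856) or number 1 at 10 µM (0.065). Its value was -3.91 without number 3 of the cAMP arrays at 0 µM and -4.03 without number 3 of the FSH arrays at 10 µM. For Cyp19a1 the difference was -4 ± 1.34 (adjusted p = 0.16) and for Star -2.11 ± 0.77 (adjusted p = 0.228). The unexposed means of Cyp19a1 include the doubted arrays numbered 2, which lay far from numbers 1 and 3. Without number 2 of the FSH arrays at 0 µM its effect with FSH was -6.1, against -4.77 with all arrays. Its difference without the pair was not analysed here, so this result does not show that HPTE acted alike on Cyp19a1. Over all probe sets limma called 584, 321 higher and 263 lower. The block gave 1847, 894 higher and 953 lower. Numbers 1 and 2 alone gave 172, 138 higher and 34 lower, and leaving out the pair of doubted arrays 1123, 425 higher and 698 lower. Which direction held more calls therefore depended on the fit and the arrays.

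Genes that responded to cAMP showed how far the response to FSH was lost. The 207 genes raised at least 2-fold by cAMP fell by a median of 1.5 on the log2 scale at 10 µM HPTE with FSH (quartiles -2.13 and -1.03), 99.5% of them lay below 0, and 163 were called lower (camera p = 2.61e-90, p = 4e-06 with an estimated correlation). At 5 µM the median was -1.34 (p = 5.73e-06 with an estimated correlation) and at 1 µM -0.387 (p = 0.00217 with an estimated correlation). The 467 genes lowered by cAMP had a median of 1.22 at 10 µM with FSH, and 350 were called higher. The sets share no array with these comparisons, but they were chosen on arrays of this series, so their direction with FSH is not independent evidence. In the other direction, the 315 genes raised by FSH had a median of -0.15 at 10 µM HPTE with cAMP (p = 0.00589, but p = 0.548 with an estimated correlation), with 17 called higher and 16 lower. That median was 0.113 without the pair of doubted arrays. It was 0.068 without number 2 and -0.29 without number 3 of the unexposed cAMP arrays, and -0.236 without number 1 of the unexposed FSH arrays. As a score per array, which for unexposed basal and cAMP arrays follows from the choice of the genes, the genes raised by cAMP stood 1.89 ± 0.1 above basal with FSH alone (SD, n = 3), 1.49 ± 0.48 at 1 µM, 0.37 ± 0.21 at 5 µM and 0.19 ± 0.16 at 10 µM, while with cAMP they stood at 1.78 ± 0.19, 1.82 ± 0.04, 1.78 ± 0.11 and 1.47 ± 0.03.

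**Figure D4:**
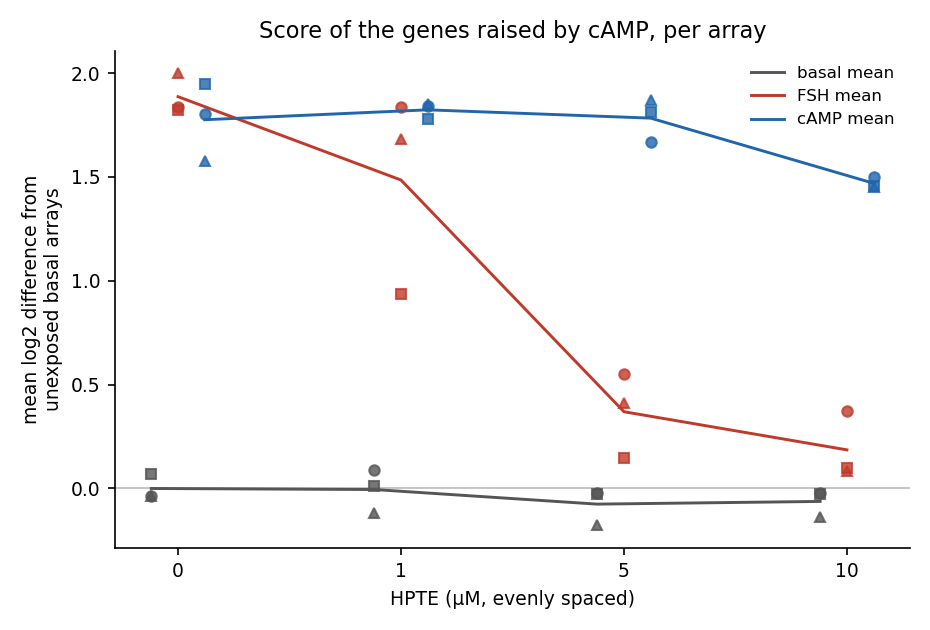
Mean log2 difference from the unexposed basal arrays over the genes raised at least 2-fold by cAMP (vertical axis) at each HPTE dose (horizontal axis, µM), with 1 point per array shaped by number (circle 1, square 2, triangle 3) and lines through group means. With FSH the mean went from 1.89 at 0 µM to 0.19 at 10 µM, and with cAMP from 1.78 to 1.47; number 2 of the FSH arrays at 1 µM lay at 0.936.

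Stimulated and basal cells were also compared at each HPTE dose, comparisons chosen after seeing the data. At 10 µM cAMP still raised Cyp11a1 by 4.79 ± 0.79 (27.7-fold, adjusted p = 0.000118), Inha by 3.09 ± 0.35 and Nr5a1 by 1.85 ± 0.23, and lowered Acta2 by 24.3-fold (-4.6 ± 0.55). With FSH at 10 µM Cyp11a1 stood 0.96 ± 0.79 above basal cells (adjusted p = 1) and Inha 1.21 ± 0.35 (adjusted p = 1). At 1 µM FSH raised Cyp19a1 by 5.83 ± 0.95 (56.8-fold, adjusted p = 0.000337) and Crabp2 by 5.2 ± 0.53. Without number 2 of the FSH arrays at 1 µM they were at 6.59 and 5.79. For FSH limma called 941 at 1 µM, 433 higher and 508 lower, 1 at 5 µM and 0 at 10 µM, with 424 and 497 at an unadjusted p under 0.05 at the higher doses. These 2 unadjusted counts were fewer than expected without any effect, so the few calls do not show that no response was left. The block gave 2489, 5 and 1, 1139 of the first higher, and numbers 1 and 2 alone 264, 0 and 0, 115 of the first higher. The count at 1 µM was 347, 1490 and 486 without numbers 1, 2 and 3 of the FSH arrays and 578 without number 3 of the basal arrays, and that at 5 µM was 11 without number 2 of the FSH arrays. For cAMP limma called 2704, 2509 and 1918 at 1, 5 and 10 µM; the block gave 5554, 5272 and 3977, and numbers 1 and 2 alone 2310, 2125 and 1865. Of the probe sets called for cAMP at 0 µM, 462 higher and 790 lower were called the same way at 10 µM, where independent calls would give 22.8 and 48.1; these comparisons share no arrays.

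Of the 5 marker lists of other cell types, 1 passed in 1 comparison. In the theca and stroma list, 1 of whose 12 genes (Cyp17a1) is also in the steroidogenesis list, 1 rose and 1 fell at 10 µM with cAMP (1 and 2 adjusted over the list alone; median -0.264, adjusted p = 0.0264, but adjusted p = 0.25 with an estimated correlation); the collagen Col1a1 changed by -1.93 ± 0.37. That list did not pass in the other main comparisons (adjusted p = 0.246 for FSH, 0.29 for cAMP, 0.185 for 10 µM in basal cells and 0.937 with FSH). The macrophage list did not pass (adjusted p = 0.102, 0.246, 0.932, 0.185 and 0.73 for FSH, cAMP, and 10 µM in basal, FSH and cAMP cells), although its member Cd14 fell with FSH (-1.51 ± 0.25) and with cAMP (-1.43 ± 0.25) and rose at 10 µM with FSH (1.43 ± 0.25). In the same order the adjusted p was 0.234, 0.29, 0.0609, 0.844 and 0.924 for the endothelial list, 0.528, 0.948, 0.935, 0.416 and 0.261 for the oocyte list and 0.413, 0.403, 0.935, 0.573 and 0.73 for the surface epithelium list.

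The remaining lists did not pass in any main comparison not described above. For estrogen-responsive genes the adjusted p was 0.584, 0.73, 0.447, 0.595 and 0.447 in the order just given; the median was 0.056 and the mean -0.112 at 10 µM with FSH, where 2 of 19 rose and 3 fell (2 and 4 adjusted over the list alone). Among them Nrip1, a nuclear receptor corepressor, fell by 1.25 (SE 0.12) and Rasd1, a small GTPase, by 2.47 (SE 0.28). For androgen-responsive genes the adjusted p was 0.932, 0.932, 0.754, 0.912 and 0.247; 2 of 9 rose and 2 fell at 10 µM with FSH (2 and 3 adjusted over the list alone), and camera's direction was upward while the median was -0.072. For p53 and apoptosis the adjusted p was 0.847, 0.775, 0.246, 0.447 and 0.276; Gadd45a, a growth arrest gene, rose at 10 µM with FSH (2.47 ± 0.44). Lists that passed in some comparisons only had, elsewhere, an adjusted p of 0.652 for steroidogenesis at 10 µM in basal cells, 0.247, 0.835 and 0.595 for Nrf2 with FSH, with cAMP and at 10 µM with FSH. For interferon it was 0.595 with FSH, 0.822 with cAMP, 0.912 at 10 µM in basal cells and 0.506 with FSH at 10 µM, and for hypoxia 0.935, 0.312, 0.546 and 0.506 in that order. The median, the mean and camera's direction did not all have the same sign for the androgen and hypoxia lists with FSH and with cAMP, the estrogen list with cAMP, and the ovulatory, cAMP-PKA, extracellular matrix, interferon, macrophage and surface epithelium lists at 10 µM in basal cells. The same held for the p53, hypoxia, theca and endothelial lists at 10 µM with FSH, and for the AhR, extracellular matrix, macrophage and surface epithelium lists at 10 µM with cAMP.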

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

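The tests weighed below for the lost FSH response and for the pair of arrays that look exchanged, and the RNA ratio test of the arrays numbered 3, were chosen, with the rules for reading them, after the result was seen, as were the comparisons of stimulated with basal cells at 1, 5 and 10 µM HPTE.

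The effect of 10 µM HPTE differed between stimuli by the test of the difference itself. Between FSH and basal cells 674 probe sets differed, 427 of them higher. The largest positive differences among named genes were those of Acta2 (4.23), Tnfrsf11b (4.14), Pamr1 (3.93), Ccn3 (3.77) and the receptor S1pr1 (3.73), and the largest negative ones those of Havcr1 (-4.29), Hao2 (-4.15), Prlr (-4.1), Crabp2 (-4.04) and Nxpe2 (-4.01). The call of Ccn3 was lost without number 1 of the unexposed FSH arrays (adjusted p = 0.0511) or number 3 of the exposed (0.0577), and that of Prlr without any of 10 single arrays (adjusted p from 0.0524 to 0.145). Without number 2 of the unexposed FSH arrays Havcr1 was at -5.19 and Prlr at -4.92, and without number 3 Prlr was at -3.39 and Acta2 at 4.86. Between cAMP and basal cells 40 probe sets differed, with Reg3g (2.54), Vcam1 (2.53), Cd302 (2.07), Olfml2a (1.98) and Akr1c15 (1.98) positive and Kcnd2 (-2.72), Serpinb1a (-1.79), Esm1 (-1.67) and Lrrc39 (-1.65) negative. The call of Vcam1 was lost without any of 9 single arrays (adjusted p from 0.0511 to 0.146), that of Kcnd2 without any of 8 (0.0565 to 0.0887), and that of Esm1 without number 1 of the unexposed basal arrays (0.0792), number 3 of the exposed (0.0765), number 2 of the unexposed cAMP arrays (0.058) or number 2 of the exposed (0.0521). Between FSH and cAMP cells 584 probe sets differed, 321 of them higher (425 of 1123 without the pair of doubted arrays), with Agtr2 (5.05), Tnfrsf11b (4.12), Acta2 (4.07), S1pr1 (4.04) and Akap12 (3.92) positive and Cyp11a1 (-4.64), Scarb1 (-4.07), Hao2 (-3.99), Vcam1 (-3.96) and Gstm7 (-3.81) negative. For S1pr1, 1 other probe set had the opposite sign in these comparisons. The call of Cyp11a1 was lost without number 1 (adjusted p = 0.0739) or 3 (0.0533) of the unexposed FSH arrays, number 3 of the exposed (0.0931), number 3 of the unexposed cAMP arrays (0.0856) or number 1 of the exposed (0.065). Without number 2 of the unexposed FSH arrays Agtr2 was at 6.01 and Scarb1 at -4.79, and without number 1 Agtr2 was at 4.44. Without number 3 Acta2 was at 4.71. Without numbers 2 and 3 of the unexposed cAMP arrays Akap12 was at 3.16 and 4.52. Agtr2 was at 5.67 without number 2 of these, and Cyp11a1 was at -3.91 without number 3 of these and at -4.03 without number 3 of the exposed FSH arrays.

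Of 100 random splits of the arrays in the interaction of HPTE with FSH, 3 gave as many calls as the real 674, the real one included, a share under 0.05 when the numbers are disregarded, and the highest other split gave 1285. Only 4 of the 100 parted every pair of equal numbers, the real one included, and the highest other of these gave 545. These are too few for a share under 0.05. For the interaction with cAMP 11 of 100 gave at least 40, with 1436 the highest, and for the difference between FSH and cAMP cells 7 of 100 gave at least 584, with 2158 the highest and 656 the highest among splits that parted every pair. The splits leave the responses to the stimuli in the values, so a split in line with a group may call many for that reason. For example, a split with the 3 unexposed FSH arrays together gave 862 for the first interaction. A split with the 3 exposed basal arrays together gave 859 for the second. Not every split of this kind need call many, and the cause was not tested. Splits that call several times the real count may reflect such a structure of the arrays, and the shares decide little on chance for any of these 3 counts. The fit with the number as a block gave 2102, 177 and 1847.

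With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, so the real count and the highest of the other splits are given. They were 2502 and 0 for FSH, 2228 and 1 for cAMP, and 0 and 0, 4 and 0, and 316 and 0 for 1, 5 and 10 µM HPTE in basal cells. With FSH they were 2 and 235, 2029 and 23, and 2624 and 0, and with cAMP 0 and 1, 1 and 0, and 525 and 1. At 1 µM HPTE with FSH 2 of 10 splits reached the real count; the split that called 235 set number 2 of the unexposed and numbers 2 and 3 of the exposed arrays against the rest, which points to a structure of the arrays, and no other split that parted every pair called any. For FSH against basal cells at 1, 5 and 10 µM the counts were 941 and 0, 1 and 0, and 0 and 0, and for cAMP 2704, 2509 and 1918, each with 0. For calls of gene lists they were 9 and 10 for FSH, reached by 3 of 10 splits, 7 and 8 for cAMP (3 of 10), 6 and 7 for 10 µM in basal cells (2 of 10), 7 and 10 with FSH (5 of 10), and 7 and 5 with cAMP (1 of 10). The median of the genes raised by cAMP was -1.5 at 10 µM with FSH, where the other split farthest from 0 gave -0.683, and that of the genes raised by FSH -0.15 at 10 µM with cAMP, where 7 of 10 splits lay as far from 0 and the farthest gave -0.29.

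At 10 µM HPTE the genes raised by cAMP had lost most of their response to FSH, while their response to cAMP had a median of 1.33. Exposed arrays labelled FSH that all held cells without FSH cannot be told apart from a lost response: of 4 sets of stimulus genes those raised by cAMP stood above basal cells (median 0.17, p = 0.00647 with an estimated correlation), but those raised by FSH (0.127, p = 0.0685) and those lowered by cAMP (-0.088, p = 0.514) or FSH (-0.091, p = 0.49) did not pass, and limma called no probe set. With the block, at camera's preset correlation, the last 3 sets passed too (p = 2.65e-17, 0.00266 and 0.00139). The outcome thus depended on the correlation assumed. Scores of the cAMP-raised genes were 0.374, 0.098 and 0.086 with FSH in numbers 1 to 3. In basal cells at 10 µM they were -0.024, -0.028 and -0.135. Markers alone do not decide whether other cell types took the place of granulosa cells: the highest of 5 marker list medians was 0.304, for 6 oocyte genes, of which 0 are in another list and Zp2 was the most abundant (mean log2 7.91), but the median level of 4 of the lists (5.07 to 6.01) lay under that of all values (6.1), and although the actin list (median 1.06) and Cd14 (1.43) rose, FSH had lowered both (-1.56 and -1.51), and the theca list, the only one above that level, had a median of -0.085. Other values argue against a replacement of most granulosa cells. At 10 µM limma called 0 probe sets between FSH and basal cells, but both had received HPTE, so this count alone does not decide it. In basal cells at that dose the 22 granulosa differentiation genes (median level 10.66) changed by a median of only -0.167 (camera adjusted p = 0.0319), and 0 were called. A smaller replacement is not excluded. An action of HPTE on the FSH response before cAMP stays open as well and cannot be told apart from cells without FSH: over 290 genes raised by cAMP at 1 µM the effect of 10 µM was lower with FSH than with cAMP by a median of -1.01, but this restates the medians already seen for cAMP-raised genes (-1.5 with FSH and -0.325 with cAMP). The step at which HPTE would act was not analysed here.

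At 0 µM HPTE number 2 of the FSH group and number 2 of the cAMP group looked exchanged. On 127 probe sets that separated FSH from cAMP cells at 1 µM, the FSH array lay above the cAMP array by 0.553 and 0.632 for numbers 1 and 3, but number 2 gave -0.585. At 1 µM the basal, FSH and cAMP arrays numbered 1 scored -0.076, -1.178 and -2.124. The score thus does not hold the kind of stimulus apart from the strength of the response. Different scales left by the deposited normalization are argued against, since number 2 gave -0.582 after quantile normalization. That step moved the scores little, so it does not decide on other effects of the deposited normalization. Number 2 cAMP cultures that differ at every dose are argued against too, since the larger shift of the array numbered 2 at 5 or 10 µM was 0.12 against 0.667 at 0 µM. Labels of these 2 arrays exchanged remain a candidate explanation. The split that exchanged them called 969 probe sets against 0 for the labels as given. It uses the same arrays in which the exchange was seen and is not independent evidence. All 10 splits reached that 0, which any split must. No biological explanation was tested, and the labels were kept as given in every result.

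The arrays numbered 3 stood apart from numbers 1 and 2 on the second principal component and in RNA ratios. Different scales left by the deposited normalization are argued against, since 94% of the 16638 probe sets that differed still did so in number after quantile normalization (15633). RNA integrity or amplification is a candidate explanation, since the 3' to 5' log2 ratio of Gapdh was lower by a mean of -1.08 without overlap, and the actin ratio was 1.86 to 2.61 against 2.93 to 4.14. Another share of other cell types cannot be told apart, because the medians of the 5 marker lists went from -0.444 for 13 macrophage genes, 0 of them in another list and Lyz2 the most abundant (mean log2 8.61), to 0.112 for oocyte genes, and the mean of the latter lay within 2 standard errors of 0 (0.191 ± 0.131). The labels give no biological difference between the numbers, so none was tested.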

How the results depend on the processing

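Leaving out the pair of doubted arrays, that setting with the block, the 2-level batch, the medians of gene sets without single arrays, and the comparisons of stimulated with basal cells at 1, 5 and 10 µM were chosen after the result was seen. The counts below are in the order FSH, cAMP, HPTE at 5 and 10 µM in basal cells, HPTE at 1, 5 and 10 µM with FSH and with cAMP, the interactions with FSH, with cAMP and between both, and FSH and then cAMP against basal cells at 1, 5 and 10 µM. With the replicate block they were 4984, 4709, 36, 1059, 30, 4426, 5333, 7, 23, 1810, 2102, 177, 1847, 2489, 5, 1, 5554, 5272 and 3977, and FSH against cAMP and HPTE at 1 µM in basal cells stayed at 0. Every probe set called without the block was also called with it, in the same direction. Among gene lists the block ended the call of cholesterol biosynthesis with FSH (adjusted p = 0.065) and added that of the AhR list with FSH (0.0422), and changed no other list. As many members of each list passed with the block as without or more, such as 7 higher and 1 lower of the ovulatory list with FSH against 4 and 0. With the block and the pair of doubted arrays left out they were 4953, 5363, 69, 1379, 254, 4332, 5046, 10, 627, 2864, 2679, 527, 3059, 3038, 8, 1, 6071, 5845 and 4487, and FSH against cAMP gave 2454. With the 2-level batch they were 4673, 4425, 27, 926, 7, 4120, 5027, 5, 5, 1596, 1829, 144, 1624, 2286, 5, 1, 5264, 4905 and 3679. The block and the batch take differences between numbers out of the residual spread by construction.

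Fitting the arrays of the compared groups only, which leaves fewer residual degrees of freedom, gave 1072 for FSH, 885 for cAMP, 0 and 81 for 5 and 10 µM in basal cells, 0, 610 and 1273 for 1, 5 and 10 µM with FSH, 0 and 62 for 5 and 10 µM with cAMP, 10 for the interaction with cAMP, 300 for that between FSH and cAMP, and 3 and 0 for FSH against basal cells at 1 and 5 µM. Leaving out the pair of doubted arrays gave 680 for FSH against cAMP, 23 for 1 µM with FSH, 0 and 792 for 5 and 10 µM with cAMP, and 1059, 70 and 1123 for the interactions. The genes raised by FSH then had a median of 0.113 at 10 µM with cAMP, reversed in sign; the cause was not tested. With an estimated correlation 4 lists passed for FSH, 4 for cAMP, 1 for 10 µM in basal cells and 3 with FSH, and the genes raised by FSH did not pass (median -0.15, p = 0.548).

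Leaving out each number or each array moved the counts over these ranges: 1083 to 2404 for FSH, 1062 to 2181 for cAMP, 0 to 531 for FSH against cAMP, 0 to 1 and 66 to 221 for 5 and 10 µM in basal cells, 0 to 74, 867 to 2019 and 1326 to 2463 for 1, 5 and 10 µM with FSH, and 0 to 9, 0 to 6 and 164 to 659 with cAMP. The interactions ranged from 125 to 903, 5 to 50 and 112 to 811, FSH against basal cells from 102 to 1490, 0 to 13 and 0 to 2, and cAMP from 1362 to 2310, 1280 to 2165 and 833 to 1865. The median of the genes raised by FSH went from -0.332 to 0.144, reversed without number 2 (0.144) and without number 2 of the unexposed cAMP arrays alone (0.068), and the cause was not tested. That of the genes raised by cAMP stayed between -1.86 and -1.27 at 10 µM with FSH, and was -1.21 without the pair of doubted arrays. Where an arm kept fewer arrays, the fit pooled the spread over all groups.

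Quantile normalization, eBayes with trend and robust options, leaving out dim probe sets (a highest group mean under 6.1, which kept 17297), and the mean of all probe sets of a gene moved no count by more than 1.5 times and reversed no result. Without a fold limit the sets held 465 genes raised by cAMP, with a median of -0.826 at 10 µM with FSH against -1.5, and 695 raised by FSH, with a median of -0.086 at 10 µM with cAMP against -0.15, in the same directions. Of 454 calls of named genes, none reversed under any alternative. They no longer passed in 186 cases for the compared groups only, 38 without the doubted arrays, 18 with the mean of probe sets, 12 with quantile normalization, 5 with trend and robust options and 0 with the block, in 190, 131 and 130 cases without numbers 1, 2 and 3, and in 500 of 2898 cases without a single array. In 7 of the 454 the probe set was too dim for that filter, which gave no value. On arrays the signal over background limits which changes can be detected, and dim probe sets were kept in the reported counts.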

Other observations

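The comparisons of stimulated with basal cells at single HPTE doses in this part were chosen after the result was seen. At 10 µM HPTE contractile genes were lower with cAMP than in basal cells. In the actin and smooth muscle list 12 of 16 fell and none rose (13 fell adjusted over the list alone; median -1.45, camera adjusted p = 5.33e-19 over all comparisons other than the 5 main ones, 0.00783 with an estimated correlation), among them Tagln (-4.77 ± 0.74, n = 3 arrays each, -5.37 without number 3 of the cAMP arrays) and Myl9 (-2.56 ± 0.41). Akap12, a scaffold of protein kinase A, was 30-fold lower (-4.91 ± 0.46). Vcam1, an adhesion molecule, was 14.6-fold higher (3.87 ± 0.36) and the glutathione transferase Gstm7 15.2-fold higher (3.93 ± 0.39). At 1 µM the prolactin receptor Prlr was 18.9-fold higher with FSH than in basal cells (4.24 ± 0.75, 5.1 without number 2 of the FSH arrays).

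At 10 µM HPTE in basal cells the cell surface protein Cd24 was 4.04-fold higher (2.02 ± 0.33, adjusted p = 0.000897, n = 3 arrays each), the protease inhibitor Serpinb1a 3.77-fold higher (1.92 ± 0.21; with cAMP it did not pass, at 0.12 ± 0.21, adjusted p = 0.992), and Mreg, which takes part in organelle transport, 3.19-fold lower (-1.67 ± 0.27). At 10 µM with cAMP the plasminogen activator Plat rose by 1.48 ± 0.21, and Cps1, the first enzyme of the urea cycle, changed by -1.84 ± 0.32. With FSH the vasodilator peptide adrenomedullin (Adm) was 4.05-fold higher at 10 µM (2.02 ± 0.39).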
